A study of Mus musculus with 4 samples.

How the data were processed

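Gene expression was measured in full skin punch biopsies of mice with the C57Black6/J background. The 4 groups were unwounded wild-type skin (WT), unwounded skin of mice that lack the BLT2 receptor (BLT2KO), and skin of each genotype taken 2 days after punching (WT_punched and BLT2KO_punched). BLT2, encoded by Ltb4r2, is a G protein-coupled receptor for the lipid mediators leukotriene B4 and 12-HHT and is expressed in keratinocytes. Per the labels, each biopsy was 5 mm in diameter and RNA of 3 mice was mixed for each group. Each group was therefore 1 array of a pool, and the spread between mice was not measured.

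Per the labels' protocols, the RNA was amplified and biotin-labelled, hybridised to Illumina MouseWG-6 BeadChips, scanned on the BeadStation and exported with BeadStudio, whose version is not given in the sources used here. The authors deposited an intensity per probe on a linear scale without normalization, for 45281 probes on each of the 4 arrays. A detection p-value was deposited beside each intensity, per the file headers. Its steps imply 936 negative control probes per array. A second deposited table held processed intensity values. Compared with the non-normalized values of the same array, they equalled each probe's intensity times 1 constant per array, which was 1.24 for WT, 1.12 for BLT2KO, 0.963 for WT_punched and 0.950 for BLT2KO_punched. The constants gave every array the same mean of 348, with no background subtraction. Medians of the processed values were 88.8, 79.5, 96.6 and 92.0 in the same order. How the authors chose this scaling is not given in the sources used here.

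The non-normalized intensities were processed with limma 3.58.1 in R 4.3.3. Background was estimated from the detection p-values and removed with the normexp model of neqc, an offset of 16 was added, and the 4 arrays were quantile-normalized and put on the log2 scale. Later steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Background correction bears on the size of ratios of dim genes, since the median intensity of undetected probes was 64.2 on the WT array and 62.7 on the BLT2KO array, against 92.2 and 88.7 on the punched arrays.

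Gene names came from the platform annotation of 34903 probes. Of these, 34885 had 1 gene and 18 had several and stayed unnamed, as did 10378 probes that the annotation did not list. Gene IDs of 34807 probes matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names and for which genes share a chromosome; the array files name no genome build, so no coordinates are given. The probes named 19057 genes, 9172 of them with several probes, and the probe with the highest mean over the 4 arrays stood for the gene. No probe was named for Ltb4r2, so the deleted gene was not analysed here.

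A gene was detected on an array where its probe's detection p-value was under 0.01, and entered a comparison when detected on at least 1 of the 2 arrays. Where it was detected on only 1, the other side was set at the higher of its own value and the lowest log2 value among detected probes of that array (5.23 for WT, 5.20 for BLT2KO, 5.20 for WT_punched and 5.10 for BLT2KO_punched), and its ratio is printed as "at least". The 4 comparisons were each between 2 arrays: punched against unwounded skin in each genotype, and BLT2KO against WT in each wound state. With 1 array per group, these comparisons have no replicate check, none was tested and no p-value is given. An additive model of genotype and punching over the 4 arrays was not fitted. Genes were counted at 2-fold or more in size. The error beside these counts is technical only: it is the SD of the disagreement between the log2 ratios of different probes of 1 gene, divided by the square root of 2. Such probes were read on the same 2 arrays, so error that they share, as from labelling or hybridisation, is not in this SD. It is therefore only a part of the technical error. The number of arrays limits the precision of every value.

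In advance, 26 gene lists with 622 entries were written for cell types and processes of skin, of which 563 entries were named on the array. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. The rule for named genes was fixed at the same point. It took Ltb4r2 and its neighbour Ltb4r1; the 8 highest and 8 lowest ratios of each comparison among genes detected on both arrays, with clone names left out; the 2 largest bounds each way; and up to 4 members of each list with the largest ratios. It also took Tnf, Mmp9, Il1b, Il6, Cxcl1, Cxcl2, Krt6a, Krt16 and Cldn4 in the punched comparisons, the 8 highest and 8 lowest differences of wound responses, and the 8 genes each way with the largest genotype differences shared by both states. Shared differences were ranked by the smaller of their 2 log2 ratios in size. A gene outside the rule is said to be chosen after its values were seen.

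The difference of wound responses is the log2 wound ratio in BLT2KO minus that in WT, over 9111 genes detected on all 4 arrays. The steps were tested on simulated data for the wound response in WT with 12003 genes, 200 of them changed, and noise of 0.2 on the log2 scale. Of 50 genes set 4-fold higher, 50 were counted, and of 50 set 2-fold higher, 24. Of 50 set 4-fold lower, 41 were counted, and of 50 set 2-fold lower, 16. Of 11803 unchanged genes, 12 were counted. The simulation held measurement noise but no spread between mice or pools, so this does not give the share of false counts in the real comparisons. Of 200 unchanged lists, 7 lay outside percentiles 2.5 to 97.5, as did 50 of 50 lists in which 10 of 20 genes were set at 2-fold.

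Alternatives chosen before the data were examined were no background correction, an offset of 50, median scaling in place of quantile normalization, the deposited processed values, a detection p-value under 0.05, a filter on dim probes, no detection filter and no floor, and the mean of a gene's detected probes. Added after seeing the data were counts without hair genes, without genes on the chromosome that carries Ltb4r2, and over genes detected on both arrays of a comparison.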

Results

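The series asked what the lack of the BLT2 receptor does to transcript levels in unwounded and healing skin of mice. Skin RNA was profiled on 4 arrays, 1 for each combination of genotype and wound state, each from a pool of 3 mice. No group had a replicate, so every ratio below describes the arrays compared, and none was tested. At a detection p-value under 0.01, 16383 of 45281 probes (36.2%) were detected on the WT array, 16551 (36.6%) on BLT2KO, 16512 (36.5%) on WT_punched and 17201 (38.0%) on BLT2KO_punched. Across the 9111 genes detected on all 4 arrays, log2 levels correlated at r = 0.978 between the unwounded arrays and r = 0.978 between the punched arrays. The correlation between punched and unwounded skin was r = 0.973 in WT and r = 0.964 in BLT2KO. Across both genotype and wound state, it was r = 0.972 between WT and BLT2KO_punched and r = 0.941 between BLT2KO and WT_punched. Genes are not independent replicates in these correlations.

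The deleted gene, Ltb4r2, was not analysed here, because no probe was named for it. Its neighbour Ltb4r1 encodes BLT1, the high-affinity leukotriene B4 receptor of leukocytes. Its log2 level was 10.24 in WT and 6.42 in BLT2KO skin, 14.2-fold lower, and 10.63 in WT_punched and 8.04 in BLT2KO_punched skin, 6.02-fold lower. Whether this probe lies outside the deleted part is not known, so it does not check the deletion. With punching, Ltb4r1 was 1.31-fold higher in WT and 3.07-fold higher in BLT2KO skin.

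Punched and unwounded WT skin were compared on the WT_punched and WT arrays. The neutrophil, macrophage, cytokine and interferon lists had medians above 0, with at most 6 members of each at least 2-fold higher, and 17 of 22 hair genes were at least 2-fold lower in punched skin. The hair list median was -1.65 here and -0.08 for the same comparison in BLT2KO skin. With 1 pool per group, the hair cycle stage of the WT pools cannot be told apart from punching for these genes. Of 10382 genes detected on at least 1 of the arrays, 201 were at least 2-fold higher and 154 at least 2-fold lower. Among genes detected on both, the highest ratios included Reg1, a secreted lectin-type protein (11.5-fold), Ptgis, which makes prostacyclin (7.42-fold), and Arg1, the arginase of alternatively activated macrophages (5.44-fold). The granulocyte gene Retnlg was 5.24-fold higher and the myeloid receptor Trem1 4.48-fold higher. The other 3 of the 8 highest were the striated muscle genes Tnnc1 (22.7-fold), Tnnt1 (8.60-fold) and Actc1 (6.71-fold), and the myosin light chains Myl2 and Myl3 were at least 31.4-fold and at least 30.0-fold higher. Myl2 was at a log2 level of 10.20 on WT_punched and 5.37 on BLT2KO_punched, and Myl3 was detected on WT_punched alone. Whether the ratios of these muscle genes belong to punching or to this 1 pool was not tested. The 8 lowest were the hair follicle keratins Krt28 (log2 ratio -3.17), Krt73 (8.05-fold lower), Krt35 (6.52-fold), Krt71 (5.56-fold) and Krt26 (4.83-fold), the hair protein genes S100a3 (10.6-fold) and Prr9 (8.69-fold), and the beta-defensin Defb8 (5.88-fold). Krt72 was at least 4.01-fold lower, and Sct, which encodes secretin, at least 3.64-fold lower.

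By list, 6 of 13 measured neutrophil markers were at least 2-fold higher in punched WT skin and 0 lower, with a median log2 ratio of 0.99 at percentile 100; examples are the chemokine receptor Cxcr2 (3.25-fold) and the formyl peptide receptor Fpr2 (2.84-fold). Of 23 monocyte and macrophage markers, 5 were at least 2-fold higher, among them Ccr2 (at least 3.10-fold) and Fcgr1 (2.47-fold), and the median was 0.47 at percentile 100. Of 28 cytokines and chemokines, 6 were at least 2-fold higher and 0 lower (median 0.64, percentile 100), including Osm (3.36-fold), Ccl4 (3.19-fold) and Ccl9 (2.71-fold). The median of that list ranged from 0.31 to 0.63 over the other settings. Among metalloproteinase and plasminogen genes, 3 of 21 passed 2-fold (median 0.29), with Timp1, an inhibitor of metalloproteinases, 4.12-fold higher. Of 18 type I interferon response genes, 5 were at least 2-fold higher (median 0.62, percentile 100; 0.40 to 0.62 over the other settings), such as Rsad2 (3.24-fold) and Bst2 (2.58-fold). Of 22 hair shaft and inner root sheath genes, 17 were at least 2-fold lower (median -1.65, percentile 0, and -1.74 to -0.93 over the other settings). The 11 tight junction genes were all below 0, with 0 past 2-fold (median -0.53, percentile 0, and -0.64 to -0.16 over the other settings), and 3 of 29 epidermal differentiation genes were at least 2-fold lower (median -0.32), led by Flg2 (3.22-fold). Wound-edge keratinocyte genes had a median of -0.07 at percentile 8.1, with 1 of 24 past 2-fold, Upp1 (2.29-fold higher). Of the genes fixed by name, Cxcl1 was 2.36-fold higher, Mmp9 1.98-fold, Cxcl2 1.95-fold, Il1b 1.93-fold and Tnf 1.57-fold, while Krt16 was 1.02-fold, Krt6a 1.78-fold and the tight junction gene Cldn4 1.85-fold lower. The Il6 probe was not detected on any of the 4 arrays. The probe-pair SD was 0.28 on the log2 scale, a factor of 1.21. In the deposited processed values, 85 genes were at least 2-fold higher and 49 lower.

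The same comparison in BLT2KO skin, BLT2KO_punched against BLT2KO, asked how skin without the receptor differed after punching. Members of the cytokine, chemokine and neutrophil lists were among the highest genes, and the epidermal differentiation list had a median below 0. Of 10587 genes, 328 were at least 2-fold higher and 181 at least 2-fold lower. The highest were the cytokine Osm (24.0-fold), Acod1, the itaconate-producing enzyme of activated macrophages (22.9-fold), Retnlg (19.4-fold), the neutrophil attractant Cxcl2 (17.3-fold), Il1b (15.7-fold), Ccl4 (15.3-fold), the stefin-like Cstdc4 (15.3-fold) and Ccl3 (13.7-fold). Slfn1 was at least 12.1-fold higher and Trem1 at least 7.84-fold. The lowest were Retnla, a resistin-like gene of alternatively activated macrophages (11.5-fold lower), the glutathione transferase Gsta3 (6.77-fold), the cytochrome P450 gene Cyp2e1 (5.74-fold), Inmt (3.90-fold), the carboxylesterase Ces1f (3.72-fold), Mup6 (3.67-fold), the adipocyte carbonic anhydrase Car3 (3.50-fold) and Angptl7 (3.27-fold). Mettl21c was at least 5.23-fold lower and Kazald1 at least 2.91-fold lower.

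Of 13 neutrophil markers, 9 were at least 2-fold higher in punched BLT2KO skin (median 2.23, percentile 100, and 1.38 to 2.54 over the other settings), including Fpr2 (11.5-fold) and Clec4d (10.4-fold). The macrophage list had 9 of 23 members at least 2-fold higher (median 0.83, percentile 100), led by the endotoxin co-receptor Cd14 (9.87-fold) and Arg1 (6.30-fold). Among 29 cytokines and chemokines, 12 were at least 2-fold higher and 2 lower (median 0.92, percentile 100, and 0.43 to 0.99 over the other settings). Metalloproteinase and plasminogen genes had 6 of 22 members at least 2-fold higher and 1 lower (median 0.57, percentile 100, and 0.35 to 0.65 over the other settings), with the urokinase receptor Plaur 7.18-fold, Timp1 5.58-fold and Mmp9 5.55-fold higher. The interferon list had 9 of 19 higher (median 0.95, percentile 100, and 0.50 to 1.07 over the other settings), with Irf7 at least 4.28-fold higher. Of 24 wound-edge keratinocyte genes, 5 were at least 2-fold higher, among them the matrix protein Tnc (2.68-fold), Slpi (2.53-fold) and Krt6b (2.38-fold), but the list median was 0.09 at percentile 85.5. All 31 epidermal differentiation genes had ratios below 0 and 6 were at least 2-fold lower (median -0.62, percentile 0), such as Krt2 (2.81-fold). Tight junction genes had a median of -0.35 (-0.40 to -0.15 over the other settings), and the 27 measured hair genes a median of -0.08 with 1 past 2-fold, Krtap16-3 (2.02-fold lower). Of the genes fixed by name, Cxcl1 was 6.95-fold and Tnf 4.07-fold higher, Krt16 1.41-fold higher, Krt6a 1.01-fold lower and Cldn4 1.19-fold lower. The probe-pair SD was 0.27. Higher genes made up 64.4% of those past 2-fold, against 82.1% in the deposited processed values (220 higher, 48 lower), 76.7% without background correction (191 higher, 58 lower) and 56.4% with median scaling (303 higher, 234 lower).

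The wound responses of the genotypes were then set against each other. The neutrophil, cytokine and hair lists had higher median wound ratios in BLT2KO than in WT, and the adipocyte list had a higher one in WT, under every setting tried. The skeletal muscle list had medians of -0.08 in WT and 0.00 in BLT2KO. Tnnc1, Tnnt1 and Myh8, which are not on that list, were among the genes with larger ratios in WT. Over 9111 genes, 107 had a ratio at least 2-fold larger in BLT2KO and 52 at least 2-fold larger in WT. The 8 largest differences were Defb8 (4.32 on the log2 scale), S100a3 (9.13-fold), Cxcl2 (8.85-fold), Krt28 (8.53-fold), Il1b (8.15-fold), Cstdc4 (8.04-fold), Krt73 (7.68-fold) and Osm (7.15-fold). At the other end were Ces1f (11.8-fold), the lipogenic regulator Thrsp (-3.33 on the log2 scale), Gsta3 (9.08-fold), Tnnc1 (7.71-fold), Tnnt1 (6.24-fold), Cyp2e1 (6.04-fold), Mrap (4.55-fold) and the myosin heavy chain gene Myh8 (4.38-fold). Genes at least 2-fold higher with punching numbered 200 in WT and 328 in BLT2KO among the 10043 genes measured in both, and 135 were shared, against 6.53 for independent lists. For lower genes, 63 were shared of 154 and 176, against 2.70, and 3 genes passed 2-fold in opposite directions. Since genes do not vary independently, 6.53 and 2.70 are a reference and not a test. Across genes, the ratios correlated at r = 0.70, and the major-axis slope of BLT2KO on WT was 1.24. For the 208 genes whose mean ratio over the genotypes was at least 2-fold higher, the median log2 ratio was 1.05 in WT and 1.57 in BLT2KO, and 179 had the larger ratio in BLT2KO. The same 208 genes had a median BLT2KO against WT ratio of -0.76 in unwounded and -0.20 in punched skin, so their larger wound ratio went with a lower level in unwounded BLT2KO skin. Il1b shows this: its log2 level was 10.84 in WT and 8.24 in BLT2KO before punching, and 11.79 and 12.22 after. For the 101 genes that were lower, the median difference was -0.03. These differences were not tested, and the counts of 107 and 52 ranged with the setting, from 52 and 22 without background correction to 178 and 109 with no detection filter and no floor.

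**Figure D1:**
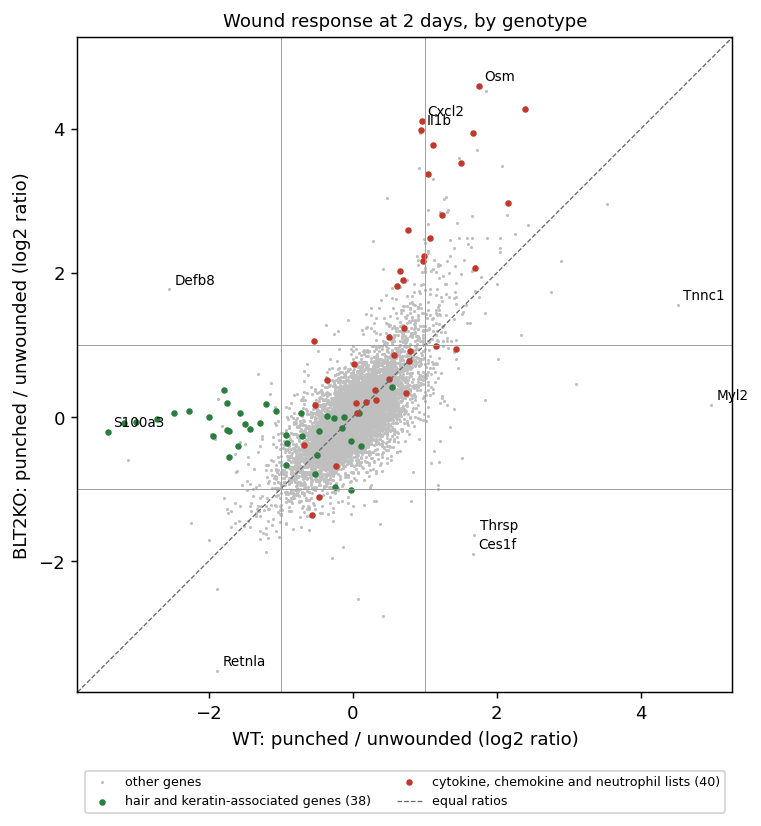
Log2 ratio of punched to unwounded skin in WT (x axis) and BLT2KO (y axis) for 10043 genes, 1 point per gene and 1 array per group, with grey lines at 2-fold and a dashed line of equal ratios. Red points of the cytokine, chemokine and neutrophil lists lie mostly above the dashed line, with Osm at 1.75 and 4.59, while green hair genes spread to the left near 0 on the y axis, with S100a3 at -3.40 in WT.

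BLT2KO and WT skin without a wound were compared to ask what the genotype alone went with. In BLT2KO skin, 23 of 27 hair genes were at least 2-fold higher, and 7 of 11 neutrophil markers and 12 of 27 cytokines and chemokines were at least 2-fold lower. Of 10235 genes, 111 were at least 2-fold higher and 120 at least 2-fold lower in BLT2KO. The 8 highest were keratin-associated protein genes, which encode the matrix between keratin filaments of the hair shaft, from Krtap4-16 (35.9-fold) to Krtap1-5 (47.6-fold) and Krtap6-2 (47.7-fold), and Krtap6-5 and Krtap4-1 were at least 52.8-fold and at least 50.1-fold higher. The lowest besides Ltb4r1 were the acute-phase gene Saa3 (9.04-fold lower), the histone chaperone gene Supt16 (7.84-fold, with a second probe at a log2 ratio of -0.32), the cytokine Il24 (7.53-fold), Cstdc4 (7.23-fold), Retnlg (7.05-fold), Il1b (6.06-fold) and Cxcl2 (5.97-fold). Chil3 and Chil4, chitinase-like genes of activated myeloid and epithelial cells, were at least 7.52-fold and at least 6.76-fold lower.

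Of 27 measured hair genes, 23 were at least 2-fold higher and 0 lower in unwounded BLT2KO skin (median 2.71, percentile 100). The 11 measured neutrophil markers were all lower and 7 were at least 2-fold lower (median -1.36, percentile 0, and -1.73 to -0.88 over the other settings), among them Clec4d (4.28-fold), S100a9 (3.96-fold) and Fpr2 (3.78-fold). Cytokines and chemokines had 12 of 27 members at least 2-fold lower and 0 at least 2-fold higher, with 6 above 0 (median -0.73, percentile 0), including Ccl3 (5.38-fold). Over the other settings that median ranged from -0.91 to -0.13, the latter without the detection filter, where undetected members count. Of 22 macrophage markers, 3 were at least 2-fold lower and 19 lay between (median -0.51, percentile 0), with Cd14 3.93-fold lower. Of 21 metalloproteinase and plasminogen genes, 6 were at least 2-fold lower and 15 lay between (median -0.42, percentile 0), with the collagenase Mmp13 4.52-fold and Mmp9 3.77-fold lower. Wound-edge keratinocyte genes had a median of -0.34 at percentile 0: Tnc was 3.94-fold, Slpi 2.76-fold and Krt6b 2.64-fold lower, whereas S100a7a was 4.11-fold higher. Epidermal differentiation genes had 29 of 31 members above 0 and 2 past 2-fold, Krt2 (at least 2.72-fold) and Krt1 (2.02-fold), with a median of 0.28 at percentile 100. Tight junction genes had a median of 0.26 (0.10 to 0.26 over the other settings) and interferon genes one of -0.39, with Oasl2 2.08-fold and Isg15 2.05-fold lower. Of 9 melanocyte markers, 3 were at least 2-fold higher, Tyrp1 (2.94-fold), Pmel (2.89-fold) and Dct (2.41-fold), and the list median was 0.19 at percentile 99.8, and 0.10 to 1.01 over the other settings. The probe-pair SD was 0.22. Which direction held more genes depended on the setting: 111 higher and 120 lower turned to 77 and 59 without background correction, 80 and 68 in the deposited processed values, 83 and 77 with an offset of 50, and 106 and 105 with the mean of probes.

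In punched skin, BLT2KO and WT were compared to ask what the genotype went with 2 days after wounding. In BLT2KO skin, 24 of 27 hair genes were at least 2-fold higher and 8 of 18 adipocyte genes at least 2-fold lower, and the neutrophil and cytokine medians lay nearer 0 than in unwounded skin. The muscle genes Myl2, Myl3, Tnnc1 and Tnnt1 were among the lowest. The skeletal muscle list holds none of these genes, so it does not speak to them. It had a median of -0.12 with 0 of 27 genes past 2-fold. Of 10540 genes, 114 were at least 2-fold higher in BLT2KO and 57 at least 2-fold lower; 48 of the 114 were detected only on the BLT2KO_punched array. The 8 highest were Krtap7-1 (87.1-fold), Krtap3-1 (75.1-fold), Krt34 (70.3-fold), Krt33b (64.1-fold), Krt86 (57.7-fold), Krtap4-7 (57.4-fold), Krtap6-2 (56.8-fold) and Krt33a (55.4-fold), all genes of the hair shaft. Krtap2-4 and Krtap19-9b were at least 66.5-fold and at least 62.4-fold higher. The 8 lowest were Myl2 (28.4-fold lower), Supt16 (8.56-fold, with a second probe at a log2 ratio of -0.17), Tnnc1 (8.08-fold), Thrsp (6.32-fold), Ltb4r1 (6.02-fold), Gsta3 (5.68-fold), the ribonuclease angiogenin, Ang (4.98-fold), and Tnnt1 (4.93-fold). Myl3 was at least 32.7-fold lower and Diaph3 at least 2.33-fold lower. These muscle genes had higher levels on the WT_punched array than on the others: the log2 level of Myl2 was 10.20 there against 5.37 on BLT2KO_punched. Tnni1, also off the list, was detected on the WT_punched array alone, at 5.82. The skeletal muscle actin gene Acta1, which is on the list, was at 14.47 and 14.39. Tnni1 and Acta1 were chosen after their values were seen.

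Of 27 hair genes, 24 were at least 2-fold higher in punched BLT2KO skin and 0 lower (median 4.87, percentile 100). Melanocyte markers had 3 of 7 members at least 2-fold higher, Pmel (4.90-fold), Mlana (3.62-fold) and Dct (3.57-fold), with a median of 0.96 at percentile 100 (0.34 to 1.40 over the other settings). Of 18 adipocyte genes, 8 were at least 2-fold lower and 0 higher (median -0.87, percentile 0): Thrsp, the lipid droplet genes Cidec (2.93-fold) and Plin1 (2.41-fold), and the adipokine Adipoq (2.48-fold) are examples. Metalloproteinase and plasminogen genes had 2 of 22 members at least 2-fold lower, Mmp10 (2.29-fold) and Mmp13 (2.28-fold), and a median of -0.27 at percentile 0. Cytokines and chemokines had a median of -0.22 at percentile 0 (-0.26 to -0.07 over the other settings), with Il24 2.51-fold lower as the single member of 29 past 2-fold. Macrophage markers had a median of -0.25 at percentile 0 and neutrophil markers one of -0.12 at percentile 8.5 (-0.14 to -0.08 over the other settings), with 0 members of either past 2-fold. Wound-edge keratinocyte genes had a median of -0.15 at percentile 0.3, and S100a7a was at least 5.61-fold higher. Tight junction genes had a median of 0.25 at percentile 99.8 (0.08 to 0.34 over the other settings), with Cldn3 1.79-fold and Cldn4 1.68-fold higher. Of the other genes fixed by name, Tnf was 1.17-fold, Mmp9 1.35-fold, Cxcl1 1.61-fold, Krt6a 1.44-fold and Krt16 1.17-fold lower, and Il1b and Cxcl2 were higher, at log2 ratios of 0.43 and 0.57. The probe-pair SD was 0.19, a factor of 1.14. Without the floor, over genes detected on both arrays, 66 genes were higher and 53 lower; in the deposited processed values, 28 were lower.

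Genotype differences that appeared in both wound states rest on separate arrays. Hair genes made up much of the shared higher side, and genes of the chromosome that carries Ltb4r2 much of the shared lower side. Of 9849 genes measured in both states, 85 were at least 2-fold higher in BLT2KO in each, against 1.28 for independent lists, and 17 were lower in each, against 0.62. Over genes detected on both arrays of a comparison, 41 were higher in each, and in the deposited processed values, 9 were lower in each. The ratios correlated across genes at r = 0.66. Genes are not independent replicates in these overlaps or in this correlation, so 1.28 and 0.62 are a reference and not a test. Of the 85 higher genes, 45 were keratin or keratin-associated protein genes or stood on the hair list. Ranked by the smaller of the 2 ratios, the largest were Krtap6-2, Krtap2-4, Krtap4-1, Krtap9-1, Krtap19-9b, Krtap1-5, Krtap6-5 and Krtap4-16. Among the others, chosen after their values were seen, were Shh, a signal of hair follicle growth (log2 ratio 1.29 unwounded and, as a lower bound, 1.06 punched), and the calcium-dependent hair enzyme gene Padi1 (3.13 and 3.08). The 17 lower genes included Supt16, Ltb4r1, Ang, the mitochondrial peptidase gene Mipep, the esterase gene Esd, Ndrg2, Samd4 and the proteasome gene Psmb5. Mipep was 4.28-fold, Esd 3.47-fold, Ndrg2 3.27-fold, Samd4 3.12-fold and Psmb5 3.07-fold lower in the state with the smaller ratio. A second probe of Supt16 had ratios of -0.32 and -0.17, and one of Ndrg2 ratios of -0.32 and 0.25, in unwounded and punched skin. By the gene table of assembly GRCm38.p6, 10 of the 17 lay on the chromosome that carries Ltb4r2, which held 332 of the 9849 measured genes (3.37%), and at most 2 lay on any other chromosome. The other 7 were Il24, Mmp10, Mmp13 and Chil4, and Saa1, Cemip and Ptx3, which were chosen after their values were seen.

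**Figure D2:**
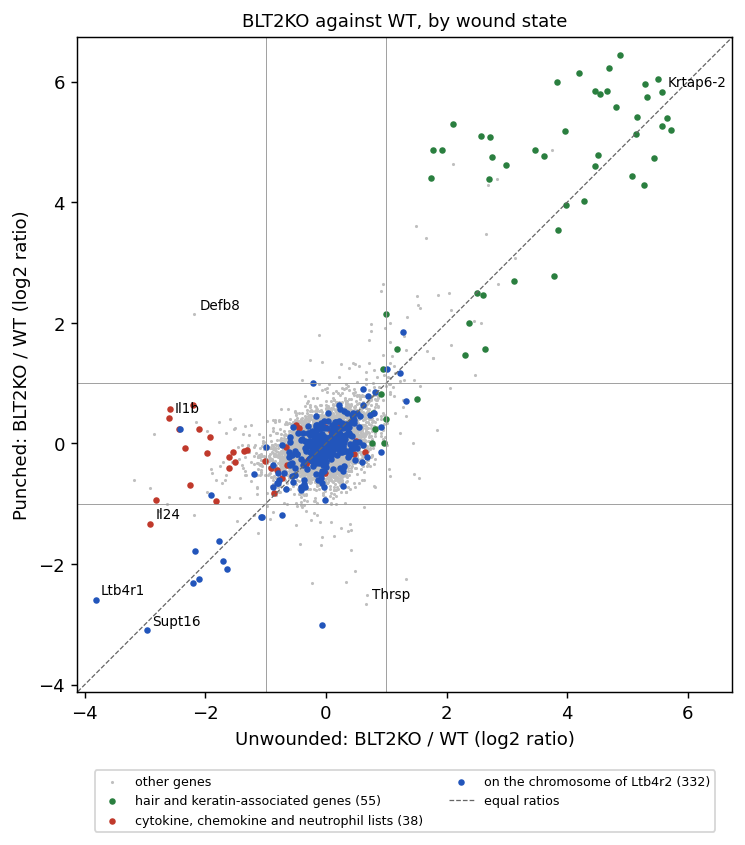
Log2 ratio of BLT2KO to WT in unwounded (x axis) and punched skin (y axis) for 9849 genes, 1 point per gene and 1 array per group, with grey lines at 2-fold and a dashed line of equal ratios. Green hair genes lie at the upper right, with Krtap6-2 at 5.58 and 5.83; red cytokine, chemokine and neutrophil genes lie mostly left of 0 and include Il1b at -2.60 and 0.43 and Il24 at -2.91 and -1.33; blue genes of the chromosome that carries Ltb4r2 include Supt16 at -2.97 and -3.10.

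The remaining lists cover other cell types and processes, and their medians are given for the wound response in WT, the wound response in BLT2KO, the unwounded genotype difference and the punched genotype difference, in that order. Adipocyte genes had medians of 0.25 and -0.50 for the wound responses and -0.02 in unwounded skin, with Thrsp at log2 wound ratios of 1.69 in WT and -1.64 in BLT2KO. Endothelial genes had medians of 0.31, 0.48, -0.37 and -0.15, and the lymphatic gene Lyve1 had wound ratios of -1.07 in WT and -1.58 in BLT2KO. Immediate early and stress genes stood at 0.15, 0.36, -0.29 and 0.11, with 6 of 23 at least 2-fold higher with punching in BLT2KO, such as Ier3 (log2 ratio 1.51) and Socs3 (1.31). For genes of BLT receptors and eicosanoid synthesis the medians were 0.20, 0.15, 0.05 and -0.17, and the thromboxane synthase Tbxas1 had a wound ratio of 1.40 in WT. Hypoxia and glycolysis genes had 0.07, 0.30, -0.32 and -0.09, and cell cycle genes -0.06, 0.13, -0.19 and -0.01. The interferon list had -0.07 in punched skin. Sebaceous gland genes stood at -0.30, -0.38, 0.23 and 0.17, basal keratinocyte markers at -0.26, -0.20, 0.03 and 0.06, and epidermal differentiation genes at 0.02 in punched skin. Fibroblast and matrix genes had 0.03, -0.05, 0.11 and 0.05, with Thbs1, an extracellular regulator of platelets and vessels, at wound ratios of 1.32 in WT and 2.87 in BLT2KO. Skeletal muscle genes had -0.08, 0.00, -0.14 and -0.12. Among immune lists, lymphocyte markers had 0.16, 0.07, 0.23 and 0.04, Langerhans and dendritic cell markers 0.07, 0.43, -0.29 and 0.02, and mast cell and basophil markers 0.40, 0.25, -0.12 and -0.02, with Hdc, the histamine-forming enzyme, at a wound ratio of 3.45 in BLT2KO. Melanocyte markers had -0.37 and -0.12 for the wound responses. Nerve and Schwann cell markers had -0.61, 0.20, -0.14 and 0.05, and red blood cell genes 0.68, -0.30, 0.46 and -0.46. Sex-linked genes had a median of 0.02 in unwounded skin and fewer than 3 detected members elsewhere. That list joins Xist with genes of the Y chromosome, so its median does not show whether the pools were matched for sex. Of these medians, the following at least 0.1 in size moved by 1.5 times or more over the other settings, and medians nearer 0 also moved by such factors. With punching in WT, eicosanoid genes ranged from 0.02 to 0.26, lymphocyte markers from -0.01 to 0.24, mast cell markers from 0.17 to 0.40, melanocyte markers from -0.59 to -0.16, nerve markers from -0.61 to -0.16, red blood cell genes from 0.40 to 0.85 and immediate early genes from 0.05 to 0.18. With punching in BLT2KO, the range was 0.08 to 0.28 for eicosanoid genes, -0.34 to -0.16 for basal markers, -0.41 to -0.24 for sebaceous genes, -0.53 to -0.33 for adipocyte genes and 0.26 to 0.46 for Langerhans and dendritic cell markers. It was 0.21 to 0.39 for mast cell markers, -0.38 to 0.22 for nerve markers, -0.42 to -0.15 for red blood cell genes, -0.25 to 0.00 for melanocyte markers and 0.07 to 0.15 for cell cycle genes. In unwounded skin, lymphocyte markers ranged from 0.00 to 0.24, Langerhans and dendritic cell markers from -0.30 to -0.14 and hypoxia genes from -0.30 to -0.16. There too, skeletal muscle genes ranged from -0.14 to -0.07, matrix genes from 0.07 to 0.17, mast cell markers from -0.13 to 0.05, nerve markers from -0.31 to -0.07 and immediate early genes from -0.30 to -0.20. In punched skin, eicosanoid genes ranged from -0.24 to -0.07, sebaceous genes from 0.10 to 0.20, skeletal muscle genes from -0.18 to -0.11 and endothelial genes from -0.18 to -0.10. Of 101 list medians, 15 changed sign under another setting, the largest of them 0.20 in size. Under another scaling or background setting this held for cell cycle genes with punching in WT, for matrix genes and lymphocyte markers with punching in BLT2KO, and for eicosanoid and adipocyte genes in unwounded skin. It also held for differentiation, basal, lymphocyte, mast cell and cell cycle lists in punched skin.

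**Figure D3:**
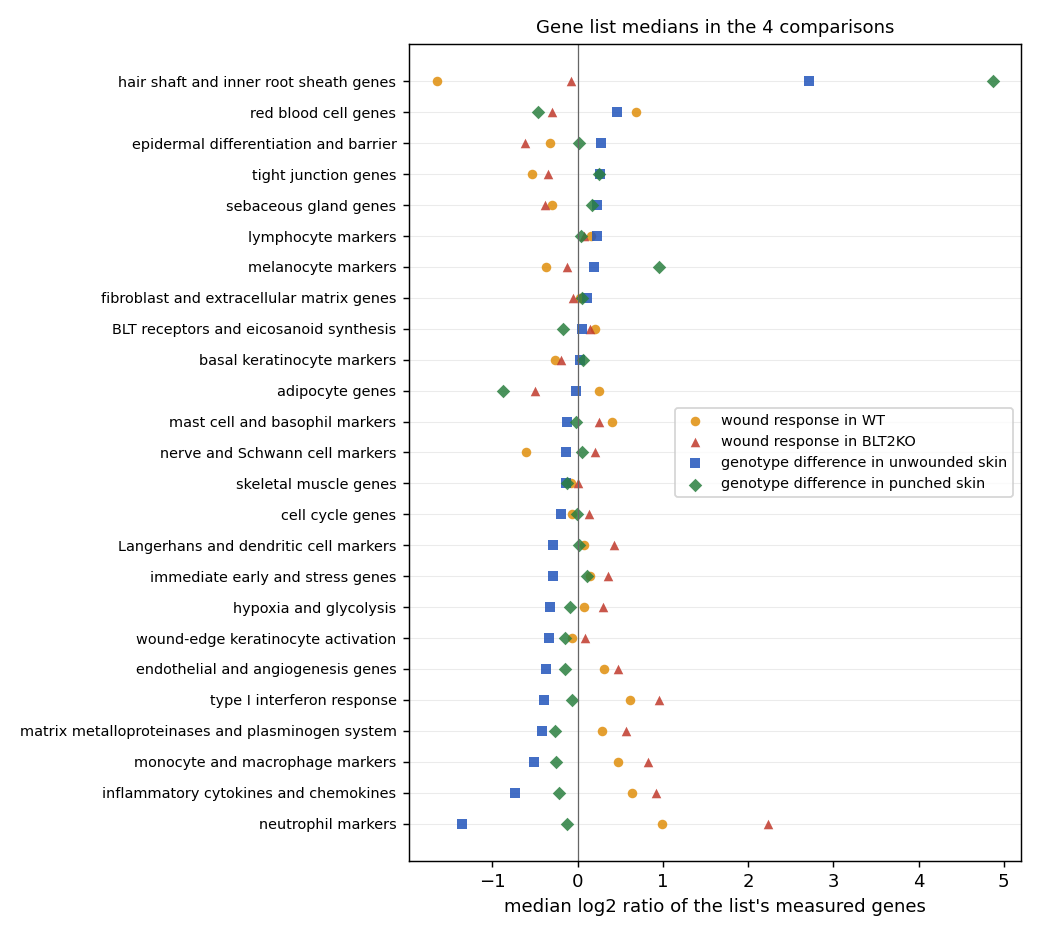
Median log2 ratio of the measured genes of 25 lists, with 1 line per list, in the 4 comparisons (symbols), with 1 array per group and a line at 0. Neutrophil markers range from -1.36 in the genotype comparison of unwounded skin to 2.23 for the wound response in BLT2KO, and hair genes from -1.65 for the wound response in WT to 4.87 for the genotype comparison of punched skin.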

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

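All tests that weigh explanations in this part were chosen after the results were seen. Some values differed in direction between genotypes or wound states, and no such difference was tested, since each rests on single arrays. The adipocyte list had a median log2 wound ratio of 0.25 in WT and -0.50 in BLT2KO. For Ces1f the wound ratio was 1.67 in WT and -1.90 in BLT2KO, for Defb8 -2.55 and 1.77, and for Thrsp 1.69 and -1.64. Between genotypes, Ces1f stood at 1.32 in unwounded and -2.24 in punched skin, and Defb8 at -2.18 and 2.14. Outside the named genes, 1765 probes with no single gene name were detected on all 4 arrays. Of these, 11 were at least 2-fold higher in BLT2KO in both states and 1 was at least 2-fold lower. These probes entered no comparison.

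Of 27 hair genes, 23 were at least 2-fold higher in BLT2KO in unwounded and 24 in punched skin. Background correction or scaling of the arrays is argued against, because the lowest hair list median over 4 such settings and both states was 2.39, with a probe-pair SD of 0.22. A larger share of epithelium in the biopsies is also argued against as the source of differences of this size: basal keratinocyte markers had a median of 0.06 in punched skin with an SD of 0.24, against 4.87 for hair genes. In unwounded skin their median was 0.03, against 2.71. There the epidermal differentiation, tight junction and sebaceous medians were 0.28, 0.26 and 0.23 and the wound-edge keratinocyte median -0.34, so a smaller difference in epithelium stays open. The hair cycle stage of the pooled mice apart from genotype stays open. Melanocyte markers, which go with hair growth, had medians of 0.96 in punched and 0.19 in unwounded skin (0.34 to 1.40 and 0.10 to 1.01 over the other settings), but an effect of genotype on hair growth predicts the same, so they cannot be told apart with 1 pool per group.

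In unwounded skin, 12 of 27 cytokines and chemokines and 7 of 11 neutrophil markers were at least 2-fold lower in BLT2KO than in WT, and 6 of the 27 lay above 0. A swap of the genotype labels between the unwounded arrays is argued against: of 12 genes of the chromosome of Ltb4r2 at least 2-fold lower in punched BLT2KO skin, 10 were also at least 2-fold lower in the unwounded BLT2KO array and 0 higher. This does not speak to a swap in both states. More neutrophils in the unwounded WT biopsies stay open: the neutrophil median of -1.36 is part of the pattern itself, so it decides nothing. Inflammation of that WT pool apart from genotype stays open: the cytokine and chemokine median was -0.22 in punched and -0.73 in unwounded skin, or -0.07 and -0.13 without the detection filter, and a genotype effect limited to unwounded skin cannot be told apart from it.

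Genes lower in BLT2KO skin in both states lay on the chromosome of Ltb4r2 for 10 of 17 (58.8%). An effect of the deletion on the nearest genes is argued against for the genes other than Ltb4r1, as 0 of 9 lay within 20 measured genes of it and the farthest lay 115 away. Flanking DNA of another strain kept with the targeted locus stays open. Of the 9, 6 lay within 83 measured genes of Ltb4r1, the median distance of that chromosome's other measured genes. That count lay between those set for and against this explanation, so it decides nothing. Sequence differences under single probes may also contribute, since other probes had a median log2 ratio of -0.14, but only 2 of the genes had such a probe. These are not rival explanations, since flanking DNA of another strain could itself carry sequence differences under probes. No sequence of the mice or probes was used here, so how far either holds was not determined. An effect of the lost receptor gives no reason for 58.8% of these genes to share the chromosome that held 3.37% of measured genes. This argues against it for the 10 genes as a set, while for any single gene it stays open.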

How the results depend on the processing

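Counts without hair genes, without the chromosome of Ltb4r2 and over genes detected on both arrays were chosen after seeing the data; the other alternatives were planned. Of the counts of genes and the slope under all alternatives, 101 values stayed within 1.5 times the reported count, or within a narrower bound for the slope. The other 33 moved further. The balance of the unwounded genotype counts turned from 48.1% higher genes to 56.6% without background correction, 54.1% in the deposited processed values, 51.9% with an offset of 50 and 50.2% with the mean of probes. The slope ranged from 1.15 to 1.30. Without background correction, 86 genes were higher and 53 lower with punching in WT and 191 and 58 in BLT2KO; 59 were lower in unwounded and 31 in punched BLT2KO skin, 8 in both states, and 52 and 22 had the larger wound ratio in BLT2KO and in WT. With an offset of 50, these were 115 and 81 in WT, 88 lower in BLT2KO, 77 lower in unwounded and 36 in punched skin, 11 in both states, and 63 and 28. In the deposited processed values, they were 85 and 49 in WT, 48 lower in BLT2KO, 68 lower in unwounded and 28 in punched skin, 9 in both states, and 53 and 23. These 3 settings leave or add a constant signal, which by construction shrinks ratios of dim genes; whether this is the whole cause was not tested. With no detection filter and no floor, 178 and 109 genes had the larger wound ratio in BLT2KO and in WT; undetected genes are then counted. Without keratin, keratin-associated protein and hair-list genes, 61 were higher in unwounded and 65 in punched BLT2KO skin and 40 in both. Prr9, Padi1 and Shh, described above as genes of hair, stayed among the 40, so these are not all unrelated to hair. Without the chromosome of Ltb4r2, 7 were lower in both. These counts drop by construction. Over genes detected on both arrays, 66 were higher in punched BLT2KO skin and 41 in both states, since genes at a floor are left out. Median scaling, a detection p-value under 0.05, the filter on dim probes and the mean of a gene's probes moved none of these counts by over 1.5 times; the dim filter left out almost no counted gene and says little. List medians and named genes were counted as moved by another rule, a change of at least the probe-pair SD (0.19 to 0.28). Medians near 0 could thus change by large factors uncounted. Among list medians, 60 values moved and 847 did not, and among named genes 640 and 3681. For named genes, 206 moved and 284 did not in the deposited processed values, 201 and 289 without background correction, and 136 and 354 with an offset of 50. No replicate could be left out with 1 array per group. The raw signal at the detection limit was 84.3 in WT, 83.9 in BLT2KO, 113.9 in WT_punched and 108.5 in BLT2KO_punched, against medians of 206.1, 217.6, 262.7 and 255.2 for detected probes. Ratios of genes near that limit are therefore compressed or bounded.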
